A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

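A pool of capped RNAs made with T7 RNA polymerase was incubated in a translation extract of budding yeast (Saccharomyces cerevisiae) and separated on a sucrose gradient, per the labels' protocols. RNA was taken from the 80S fraction, which holds RNAs bound by a ribosome with both subunits joined, and from a fraction that the labels call untranslated. Both were extracted with phenol and chloroform, pulled down through biotin, reverse transcribed, ligated to a 5′ linker and amplified, per the labels. The input RNA was the starting pool, and the label of its pulldown names the phenol and chloroform extraction alone. A comparison of a fraction with the input may therefore also hold the biotin pulldown. The 6 libraries were 3 of the 80S fraction, 2 of the untranslated fraction and 1 of the input. Groups and replicate numbers were taken from the labels. Nothing in the labels says whether replicates came from separate extracts, so p-values measure only the spread between these libraries, which may be technical.

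The deposited values are FPKM (fragments scaled to the length of the RNA and to the mapped reads of the library), 1 value for each RNA in each library, per the file headers. cutadapt and STAR are named in the submitters' processing notes, without versions. The program that computed FPKM, the genome build, the rule that selected the RNAs and the treatment of reads shared by several RNAs are not given in the sources used here. The last point matters because 4836 RNAs share their gene with another RNA of the pool and differ from it in the extent of the leader alone, as far as their names show. The leader is the part of an mRNA upstream of its start codon. Read counts and depth are unknown: 2.60% of the input values were whole multiples of the lowest input value, to within 0.001 of a step, so whole reads could not be recovered. The FPKM of a library sum to between 24779700 and 28542200. FPKM is a share of a library, so an RNA can rise because others fell. RNA length cancels when 1 RNA is compared between libraries.

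Each RNA is named by a yeast locus tag and a number. The number was read as the length of the leader in nucleotides (nt). Leader sequences were taken from the reference genome R64 (RefSeq) as that many bases immediately upstream of the annotated start codon, without introns. Of the 6962 RNAs, 6860 carried a locus tag found in the reference and 6855 (98.5%) received a sequence. The reading was checked on the sequences: the first base was A in 78.3% of leaders, against a mean A share of 40.5% over whole leaders, and the base just upstream was a pyrimidine in 96.1%, against a mean pyrimidine share of 42.1%. The sequences are those of the reference, and the synthesised RNAs may differ from them. The reference annotates coding sequences and no leaders for these genes. All coordinates are 1-based on R64, and sequences are written as DNA from 5′ to 3′ on the strand of the RNA.

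Values were transformed to log2(FPKM + 1). limma 3.58.1 in R 4.3.3 was fitted to all 6 libraries with 1 mean for each group and a mean-variance trend, and 3 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. The residual degrees of freedom were 3 and the prior degrees of freedom 5.15. The single input library was assumed to vary like the replicated fractions. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low RNAs. The filter, a mean FPKM of at least 10 and an input above 0, removed 0 RNAs. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of 26 lists, 25 held at least 5 RNAs and were tested, and the other held 2. For genes with several RNAs, the difference between the longest and the shortest leader was formed within each library and tested with limma in the same way. Leader features were related to the log2 ratio to input in each library, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Folding energies came from ViennaRNA 2.7.2 on the leader alone. With 3 libraries against 2, an exact permutation test cannot give a two-sided p under 0.1.

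The groups, tests, gene lists, alternatives and the rule for named RNAs were fixed before the data were examined. The rule named, for 80S against untranslated, the 8 RNAs with the largest rise and the 8 with the largest fall among those past the threshold in which the 3 80S libraries lay on the same side of both untranslated libraries, and for 80S against input the 5 and 5 likewise. It added the 2 highest and 2 lowest members of each gene list described, the 5 pairs of leaders with the largest difference, and RNAs of 12 chosen genes. Of these 12 genes, 4 had an RNA in the table used here (HIS4, PGK1, TDH3 and CPA1) and the others are not analysed here. The alternatives were other pseudocounts and filters, rescaling by median ratios, no trend, a replicate block, a fit without the input and leaving out each library. A count test was planned for whole-number counts and was not used, because the values are FPKM.

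Each procedure was tested on simulated data. For 80S against untranslated over 6962 RNAs, 41 of 100 RNAs simulated with a log2 change of 1 and 79 of 100 with a change of -2 were recovered, and 1 of 6762 unchanged RNAs was called. For 80S against input, 9 of 100 and 60 of 100 were recovered and 1 of 6762 was called. In the test of 2008 pairs of leaders, 13 of 100 and 77 of 100 were recovered and 2 of 1808 unchanged pairs were called. Few RNAs or pairs were changed in these simulations, while 70.4% of RNAs (80S against untranslated) and 68.5% of pairs passed in the data. The adjustment is stricter where few change, so these recoveries do not give the share that would be found in the data. In the list test, 1 of 1 shifted list and 0 of 24 unchanged lists were called. All other RNAs were unchanged in that simulation, while 70.4% differed between 80S and untranslated RNA in the data. It therefore does not show how often a shifted list would be called in these data. A scan of 4-base words over 4056 genes gave a planted difference of 0.5 as 0.52 with no other word called.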

Results

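The data measured how a pool of yeast mRNA leaders, the stretches upstream of the start codon, was shared between ribosome-bound and unbound RNA in a cell-free translation extract. The pool comprised 6962 RNAs from 4134 genes. A single RNA stood for 2126 genes, and 2008 genes had 2 or more RNAs that differ in leader length, up to 6 for 1 gene. Leaders were 13 to 115 nt long with a median of 45 nt. Abundance was given as FPKM in 3 libraries of the 80S fraction, 2 of the untranslated fraction and 1 of the input. Median FPKM was 2265, 2149 and 2191 in 80S replicates 1, 2 and 3, 2098 and 2049 in untranslated replicates 1 and 2, and 3112 in the input.

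Replicates of a fraction resembled each other far more than the fractions did. Across RNAs, which are not independent replicates, Pearson's r of log2 FPKM was 0.972 between 80S replicates 1 and 2, 0.980 between 1 and 3, and 0.972 between 2 and 3. It was 0.926 between the untranslated replicates. Between an 80S and an untranslated library r lay between 0.498 and 0.536. The median SD between replicates was 0.18 on the log2 scale in the 80S fraction and 0.26 in the untranslated fraction. It was larger for the third of RNAs with the lowest mean (0.21 and 0.28) than for the third with the highest (0.16 and 0.23), so differences of low RNAs carry more error.

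The comparison of the 80S with the untranslated fraction asks which RNAs lay with a ribosome rather than in the untranslated fraction. The RIM101 RNA with an 87 nt leader, from the gene of a repressor in the alkaline pH response, had the largest rise: its FPKM was 14423 ± 1590 (SD, n = 3) in 80S and 652 ± 227 (SD, n = 2) in untranslated RNA, a 22.7-fold difference. The RNA of GUS1, the glutamyl-tRNA synthetase, with a 15 nt leader had the largest fall: 853 ± 306 in 80S against 16533 ± 3635 in untranslated RNA, 20.1-fold. PAN5 (30 nt), an enzyme of pantothenate synthesis, was 21.8-fold higher in 80S, and NRG2 (83 nt), a repressor of glucose-repressed genes, was 18.2-fold lower. Of the 6962 RNAs, 2689 were higher in 80S and 2215 lower at an adjusted p under 0.05 in limma, 70.4% in all. The higher RNAs made up 54.8% of these calls, and 49.9% after rescaling by median ratios, so the excess of higher RNAs depended on the scaling. At 2-fold or more, 1913 were higher and 1638 lower, and at 4-fold or more 551 and 670.

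The median log2 change of all RNAs was 0.18, and it was 0.03 after each library was rescaled by median ratios, so changes near 0 depend on the scaling. No named RNA changed sign under that rescaling. The RIM101 leader lies at 51024 to 51110 on the plus strand of chromosome VIII, and its log2 change was 4.50 with a standard error (SE) of 0.24 (limma, adjusted p = 1.127e-05). The PAN5 leader lies at 225170 to 225199 on the minus strand of chromosome VIII, with a log2 change of 4.45 (SE 0.49, limma, adjusted p = 9.731e-05). The other 6 of the 8 largest rises were SKS1 (34 nt, a protein kinase, 16.8-fold), YJR015W (16 nt, 16.4-fold), ARV1 (109 nt, a protein of sterol homeostasis, 15.3-fold), FYV8 (59 nt, 13.7-fold), RTF1 (75 nt, a subunit of the Paf1 transcription complex, 12.7-fold) and GAL10 (25 nt, the galactose epimerase, 12.1-fold). The untranslated replicates differed for some of these. Without untranslated replicate 1 or 2, the log2 change was 5.45 or 2.43 for ARV1, 5.42 or 3.47 for PAN5, and 3.36 or 4.72 for YJR015W, and each still passed the limma threshold.

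**Figure D1:**
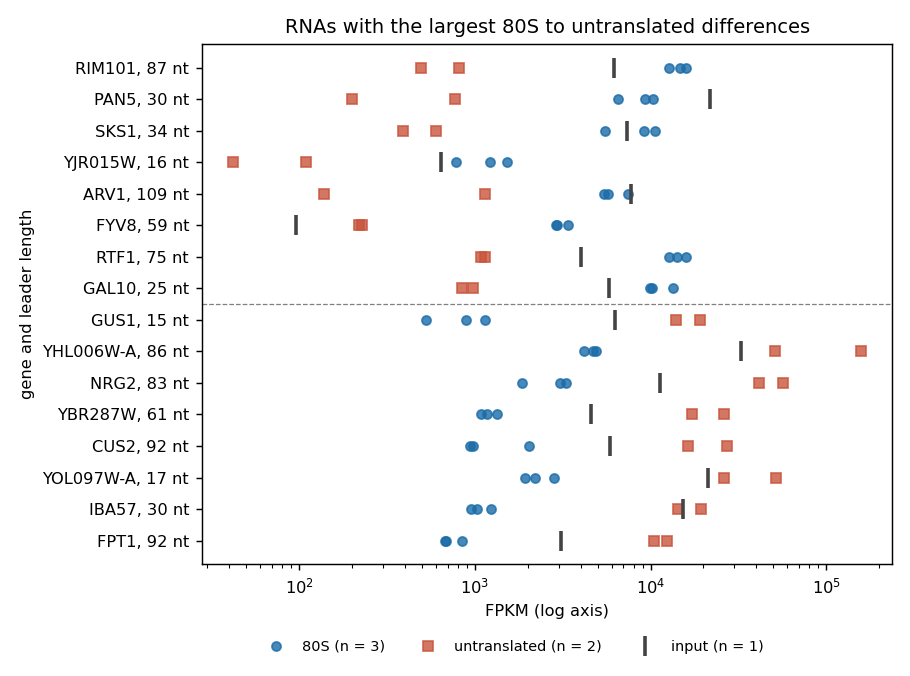
FPKM (log axis) of the 8 RNAs with the largest rise and the 8 with the largest fall in 80S against untranslated RNA, with circles for 3 80S libraries, squares for 2 untranslated libraries and a bar for the input. Circles and squares of an RNA do not overlap, which the rule that chose these RNAs required. The mean for RIM101 was 14423 in 80S against 652 in untranslated RNA.

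The GUS1 leader lies at 39008 to 39022 on the plus strand of chromosome VII and reads ATAGAAGGGATCAAG in the reference. Its log2 change was -4.33 (SE 0.32, limma, adjusted p = 1.769e-05), and its input FPKM of 6314 lay between the fractions. The NRG2 leader lies at 370700 to 370782 on the minus strand of chromosome II, with a log2 change of -4.19 (SE 0.27, limma, adjusted p = 1.323e-05). Other large falls were those of YBR287W (61 nt, 17.8-fold), CUS2 (92 nt, a splicing factor, 17.2-fold), YOL097W-A (17 nt, 16.1-fold), IBA57 (30 nt, a mitochondrial iron-sulphur cluster protein, 15.5-fold) and FPT1 (92 nt, 15.5-fold). The remaining RNA of this group, YHL006W-A with a number of 86, matched no locus tag in the reference used here, so its position is not given. It was 19.6-fold lower in 80S, but its untranslated FPKM of 104346 ± 75586 (SD, n = 2) differed between replicates, and the log2 change was -3.47 without untranslated replicate 1 and -5.11 without replicate 2.

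Among the genes chosen in advance, 3 had higher FPKM in 80S and 1 had lower. HIS4, an enzyme of histidine synthesis, has its 60 nt leader at 68334 to 68393 on the minus strand of chromosome III. It stood at 4434 ± 306 (SD, n = 3) in 80S and 438 ± 15.5 (SD, n = 2) in untranslated RNA, 10.1-fold higher (limma, adjusted p = 1.127e-05). The glycolytic genes TDH3 (39 nt) and PGK1 (40 nt) were 5.67-fold and 3.44-fold higher (limma, adjusted p = 2.296e-05 and 5.266e-05). Both RNAs of CPA1, a subunit of carbamoyl phosphate synthetase, were lower in 80S. The 109 nt leader was 4.93-fold lower and the 76 nt leader 6.05-fold lower (limma, adjusted p = 8.37e-05 and 5.79e-05).

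RNAs of most functional groups went in both directions. In the vacuolar ATPase, the proton pump of the vacuole, 16 of 23 RNAs were higher in 80S, 3 were lower and 4 did not pass. VMA2 (64 nt, log2 2.66) and VMA9 (25 nt, 2.46) were highest, and VMA1 (98 nt, -1.88) and VMA4 (31 nt, -2.12) lowest. In the respiratory chain and ATP synthase, 26 of 50 RNAs were higher and 7 lower, from QCR7 (42 nt, 2.73) and ATP3 (70 nt, 2.60) to COX4 (109 nt, -2.02) and ATP15 (30 nt, -2.33). Of 14 RNAs of the tricarboxylic acid cycle 8 were higher, among them LPD1 (79 nt, 2.73) and CIT1 (100 nt, 1.69), and 2 were lower, IDH1 (105 nt, -1.20) and KGD2 (64 nt, -1.40). Ergosterol synthesis had 18 of 33 RNAs higher and 8 lower. ERG3 (57 nt) stood at 2.95, or 3.73 and 2.18 without untranslated replicates 1 and 2, and ERG6 (34 nt) at 2.64, while the 2 lowest RNAs were both of ERG7 (66 nt, -1.97, and 37 nt, -3.49). Autophagy genes had 22 of 40 RNAs higher and 8 lower, from ATG27 (38 nt, 2.76) and ATG17 (52 nt, 2.43) to ATG18 (94 nt, -2.38) and ATG22 (76 nt, -3.12). In the proteasome, 31 of 60 RNAs were higher and 15 lower. The PUP2 RNAs (47 nt, 3.00, and 60 nt, 2.90) and those of PUP1 (65 nt, -3.21) and RPN9 (32 nt, -3.24) marked the ends.

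Among cell wall genes 16 of 27 RNAs were lower in 80S, 3 were higher and 8 did not pass, and the list as a whole did not pass against the other RNAs (limma's camera, adjusted p = 0.0789). CCW12 (43 nt, log2 -3.01) and SCW4 (107 nt, -2.79) were lowest, and CRH1 (55 nt, 1.03) and GAS1 (97 nt, 1.02) highest. Elongation and termination factors had 13 of 23 RNAs lower and 5 higher. EFB1 (33 nt, -3.19) and TEF4 (25 nt, -2.69), both of the exchange factor of elongation factor 1, were lowest. TEF1 (31 nt, 1.25), elongation factor 1 itself, was highest. YEF3 (40 nt) stood at 0.84, and its limma call was lost without 80S replicate 3 (0.74, adjusted p = 0.0564) or without untranslated replicate 2 (0.58, adjusted p = 0.0603). Nuclear pore genes had 13 of 26 RNAs lower and 5 higher, from NUP116 (75 nt, -3.18) and NUP84 (62 nt, -2.31) to NUP42 (58 nt, 1.42) and NUP159 (84 nt, 1.21).

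The translation machinery was split. Of 182 RNAs of cytosolic ribosomal proteins 70 were higher in 80S and 45 lower, with RPS27B (69 nt, log2 2.63) and RPS8B (19 nt, 2.43) highest and RPL4A (16 nt, -2.87) and RPS25A (20 nt, -3.25) lowest. Mitochondrial ribosomal proteins had 32 of 103 RNAs higher and 37 lower, from MRPS16 (27 nt, 3.14) and RSM7 (55 nt, 2.66) to MRP10 (24 nt, -3.11) and MRPS28 (49 nt, -3.42). Initiation factors had 16 of 38 higher and 13 lower. Their highest RNAs were both of CAF20, a protein that binds the cap-binding factor (25 nt, 2.21, and 42 nt, 2.09), and the lowest were of the eIF3 components NIP1 (56 nt, -3.02) and HCR1 (49 nt, -3.91). Aminoacyl-tRNA synthetases had 10 of 21 higher and 6 lower, from SES1 (46 nt, 2.26, and 22 nt, 1.73) to FRS2 (59 nt, -1.97) and GUS1. Ribosome assembly genes had 42 of 132 higher and 50 lower, from NOC4 (23 nt, 2.51) and UTP5 (35 nt, 2.18) to RRP45 (80 nt, -3.29) and NOP13 (36 nt, -3.34).

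Metabolic and stress genes were also divided. Glycolysis and fermentation had 8 of 23 RNAs higher and 7 lower, from GPM1 (23 nt, log2 3.26) and PYK2 (98 nt, 2.97) to GLK1 (56 nt, -1.72) and PGI1 (42 nt, -1.74). Amino acid biosynthesis had 45 of 111 higher and 39 lower. HIS4 (3.33) and TRP1 (34 nt, 3.03, or 3.87 and 2.20 without untranslated replicates 1 and 2) were highest, and both RNAs of ARO7 (75 nt, -3.18, and 32 nt, -3.68) lowest. Chaperones had 15 of 37 higher and 16 lower, from CPR6 (31 nt, 3.09) and HSP82 (32 nt, 2.64) to the RNAs of STI1 (73 nt, -3.17, and 86 nt, -3.59). Oxidative stress defence had 9 of 28 higher and 5 lower, from GPX1 (111 nt, 2.49) and CTA1 (50 nt, 2.31) to GPX2 (79 nt, -2.82) and GRX1 (64 nt, -2.96). Plasma membrane transporters had 14 of 33 higher and 9 lower, from STL1 (28 nt, 3.54) and HXT4 (75 nt, 2.49) to PTR2 (94 nt, -2.62) and TAT2 (66 nt, -3.02). Genes reported to hold upstream open reading frames had 12 of 21 higher and 5 lower, from ARV1 (3.94) and SCO1 (49 nt, 2.18) to URA1 (42 nt, -3.23) and IMD4 (76 nt, -3.65).

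The remaining lists also had RNAs in both directions. Cell cycle regulators had 5 of 25 RNAs higher and 8 lower, from SWE1 (93 nt, log2 2.82) and SWI6 (33 nt, 1.72) to the RNAs of CLB4 (32 nt, -2.53, and 59 nt, -1.80). The latter stood at -1.02 and -2.57 without untranslated replicates 1 and 2. Histones had 3 of 8 higher and 2 lower. HTZ1 (98 nt, 1.83) and HTA1 (75 nt, 1.83) were highest and HTB2 (23 nt, -2.34) lowest. HTB1 (34 nt, -0.76) lost its limma call without 80S replicate 2 (adjusted p = 0.0908), 80S replicate 3 (0.0882) or untranslated replicate 2 (0.0643). Transcription factors had 15 of 44 higher and 13 lower, from SWI5 (111 nt, 2.20) and INO2 (105 nt, 1.92) to DAL81 (18 nt, -3.07) and GAT1 (64 nt, -3.13). Signalling kinases had 3 of 15 higher and 4 lower, from SLT2 (37 nt, 1.35) and PKH1 (101 nt, 1.30) to STE11 (30 nt, -2.0) and YPK2 (69 nt, -2.13). Secretory pathway genes had 17 of 48 higher and 18 lower, from SEC39 (44 nt, 2.41, and 55 nt, 2.35) to SEC17 (49 nt, -2.52) and SEC11 (36 nt, -2.65).

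**Figure D2:**
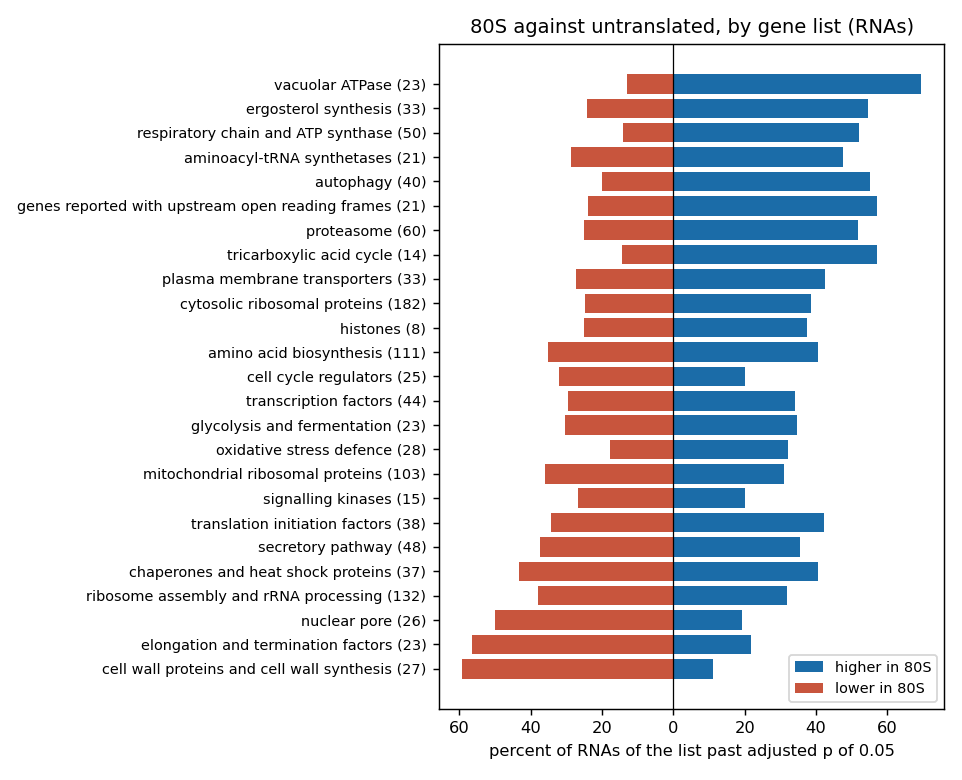
Percent of RNAs of each of 25 gene lists (number of RNAs in parentheses) past an adjusted p of 0.05 in 80S against untranslated RNA, with bars to the right for RNAs higher in 80S and to the left for RNAs lower. Each list had RNAs in both directions, with 16 of 23 higher for the vacuolar ATPase and 16 of 27 lower for cell wall genes.

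No list differed from the other RNAs at an adjusted p under 0.05 in limma's camera, with 0 of 25 lists past it at the preset correlation, 0 at an estimated correlation and 5 at an unadjusted p under 0.05. Cell wall genes came nearest, with a median log2 change of -1.14 relative to all RNAs (camera, adjusted p = 0.0789, and adjusted p = 0.868 with an estimated correlation). Without 80S replicate 3 they passed as lower in camera (adjusted p = 0.0304), but not with an estimated correlation (adjusted p = 0.938). They were followed by the respiratory chain (median 0.64, adjusted p = 0.155 in limma's camera), the elongation factors (-1.02, 0.163) and the vacuolar ATPase (0.91, 0.163). This order changed with 1 RNA per gene, a setting added after the data were seen. Cell wall genes, the nuclear pore and the tricarboxylic acid cycle then shared the lowest adjusted p in camera, 0.270. The elongation factors and the vacuolar ATPase stood at 0.490 and the respiratory chain at 0.725. fry, which asks whether the RNAs of a list move on balance in 1 direction without setting them against others, called 14 lists. Adjusted over the list alone, the counts of RNAs changed in 4 lists, by at most 2 RNAs. For glycolysis (median -0.08, mean 0.30) and oxidative stress defence (-0.13, 0.13) the median lay below and the mean and the camera direction above the pool.

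RNAs of 1 gene, which differ in their leader as far as their names show, often differed in their 80S to untranslated ratio. For ARF2, a small GTPase of vesicle traffic, the RNA with the 35 nt leader stood at 4778 ± 363 in 80S (SD, n = 3) and 731 ± 103 in untranslated RNA (SD, n = 2), while the RNA with the 102 nt leader stood at 316 ± 50.03 and 2223 ± 834. The 80S to untranslated ratio of the short leader was 44.6-fold that of the long one. For ENB1, an iron-siderophore transporter, the 35 nt leader had a 43.7-fold higher ratio than the 22 nt leader. Of 2008 genes with such pairs, the longest and shortest leader differed in 1375 (68.5%) at an adjusted p under 0.05 in limma, and 1442 at an unadjusted p under 0.05. The longer leader had the higher ratio in 701 and the lower in 674. The difference was 2-fold or more in 1093 and 4-fold or more in 470, and 330 genes had 1 RNA higher and the other lower in 80S.

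The pair of ARF2 lies on the plus strand of chromosome IV, at 216427 to 216528 for the long leader and 216494 to 216528 for the short. The 67 nt that only the long leader holds read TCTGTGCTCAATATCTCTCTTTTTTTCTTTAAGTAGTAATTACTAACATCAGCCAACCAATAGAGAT, and the log2 difference between long and short was -5.48 (SE 0.26, limma, adjusted p = 1.024e-05). The input FPKM of the long ARF2 RNA was 23.9, the lowest value of that library, and against the input the difference had the opposite sign, 2.82. For ENB1, on the minus strand of chromosome XV at 21312 to 21346, the 13 nt ATAGCAAAAAAGT separated the leaders, with a log2 difference of 5.45 (SE 0.20, limma, adjusted p = 8.616e-06). For POM152, a nuclear pore membrane protein, the 58 nt leader exceeded the 32 nt leader 38.8-fold, and the 26 nt AATTCAAAACGGATTATAGATTTATC set it apart (chromosome XIII, 527746 to 527803, plus strand). For SNU71, a component of the U1 splicing particle, the 42 nt leader had a 38.6-fold lower ratio than the 23 nt leader, with AAGCTCATAAAAGTTCCTT as the added 19 nt (chromosome VII, 514512 to 514553, plus strand). For VPS36, of the ESCRT-II sorting complex, the 102 nt leader exceeded the 75 nt leader 35.7-fold, with the 27 nt GAAAAACAAAAAAGCAGAGAAAAGGTC (chromosome XII, 954908 to 955009, plus strand).

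**Figure D3:**
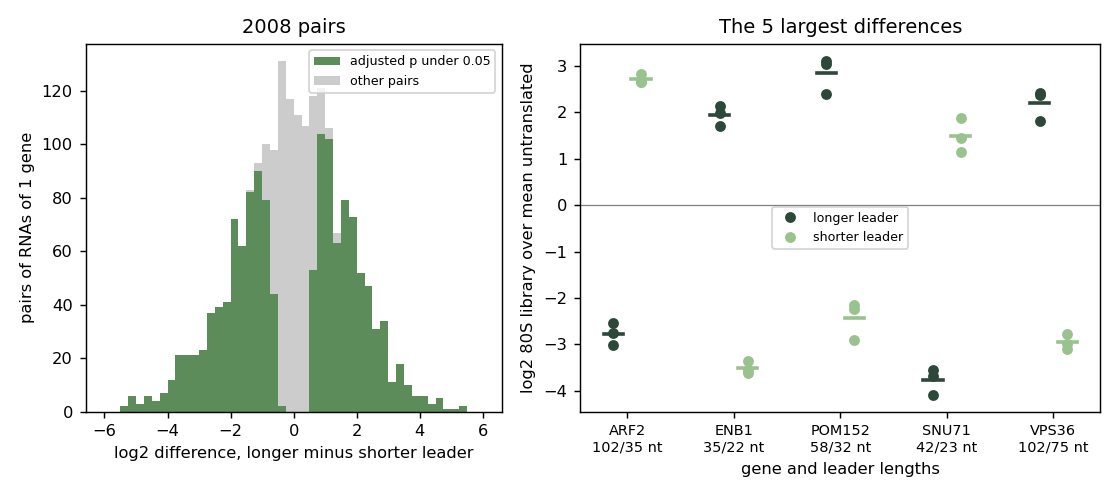
Left, number of gene pairs (vertical axis) by the log2 difference in 80S to untranslated ratio between the longest and the shortest leader, with pairs past the threshold in green. Right, log2 ratio of each of 3 80S libraries to the mean untranslated value for both leaders of the 5 pairs with the largest difference, with lines at the means, in which the shorter leader was higher for ARF2 and SNU71 and the longer for ENB1, POM152 and VPS36.

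Differences were frequent at each length difference. Of pairs up to 20 nt apart 452 of 705 (64.1%) passed the threshold, of those 21 to 40 nt apart 565 of 789 (71.6%), and of those more than 40 nt apart 358 of 514 (69.6%). How the authors' counting assigned reads shared by RNAs of 1 gene is not given, and misassigned reads would move such differences. Of the 1375 pairs past the threshold, 358 (26.0%) had a difference of the opposite sign when 80S was set against the input.

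Against the input, the question is how abundant each RNA was in 80S relative to the starting pool. MEH1, a subunit of the EGO complex at the vacuole, had the largest rise: its 17 nt leader RNA stood at 1198 ± 251 FPKM in 80S (SD, n = 3) and 23.9 in the input, 47.3-fold. MNN4, a regulator of mannose phosphate transfer to glycans, had the largest fall: its 61 nt leader RNA stood at 368 ± 27.5 in 80S and 10896 in the input, 29.6-fold. In limma 1399 RNAs were higher in 80S than in the input and 2314 lower at an adjusted p under 0.05 (53.3%), of which 980 and 1920 by 2-fold or more. The input is 1 library, so its own spread was not measured and these p-values take it from the spread within the fractions. The higher RNAs made up 37.7% of these calls, and 48.9% after rescaling by median ratios, which moved the median log2 change from -0.25 to -0.01.

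The other 4 largest rises were those of FYV8 (59 nt, 31.8-fold), IRS4 (76 nt, 31.0-fold), NSE3 (39 nt, a subunit of the Smc5-Smc6 complex, 28.5-fold) and HSU1 (96 nt, 27.3-fold). All 5 had low input values, from 23.9 FPKM for MEH1 to 95.6 for FYV8, where the median was 3112. The value of MEH1 is the lowest of the input library and is shared by 12 RNAs, and NSE3, HSU1 and FYV8 stood at 2, 2 and 4 times that value, so these folds rest on the bottom of 1 library. MEH1 and NSE3 did not differ between 80S and untranslated RNA at the threshold (log2 0.29 and 0.71, limma, adjusted p = 0.424 and 0.136), and HSU1 was lower in 80S (-0.65). The largest falls besides MNN4 were those of YHR071C-A (24.8-fold, without a locus in the reference used here), DFM1 (50 nt, of the pathway that degrades misfolded proteins of the endoplasmic reticulum, 24.8-fold), MDL2 (23 nt, a mitochondrial transporter, 23.7-fold) and SOM1 (39 nt, a subunit of the inner membrane peptidase, 23.1-fold). The MNN4 leader lies at 67467 to 67527 on the minus strand of chromosome XI, and the MEH1 leader at 451417 to 451433 on the plus strand of the same chromosome. Their log2 changes were -4.89 (SE 0.26) and 5.57 (SE 0.39), with adjusted p = 0.0001531 and 0.0001733 in limma.

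Against the input, 18 of 27 cell wall RNAs were lower in 80S and 1 was higher, with a median of -0.93 relative to all RNAs, and of 23 RNAs of elongation and termination factors 16 were lower and 3 higher, with a median of -0.89. Both passed in limma's camera (adjusted p = 0.0476 for each), and both calls were lost with an estimated correlation (adjusted p = 0.983 for each). With 1 RNA per gene, a setting added after the data were seen, the call for cell wall genes was lost (camera, adjusted p = 0.141) and that for elongation and termination factors kept (adjusted p = 0.0472). Without 80S replicate 1, 80S replicate 2, untranslated replicate 1 or untranslated replicate 2, 0 lists passed. No list was higher. Adjusted over the list alone, 20 cell wall RNAs were lower in place of 18, and 11 of the 25 lists changed their counts, by at most 2 RNAs.

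The series title speaks of a wide range of regulation, read here from ratios to the input, which spread widely in both fractions. The untranslated ratio does not measure recruitment and spread about as widely, so the 80S ratio cannot be read as recruitment alone. It also holds whatever moved both fractions against the input. The 80S to input ratio at the 99th percentile of RNAs was 98.1 ± 18.6 times that at the 1st percentile (SD, n = 3 libraries). The same range in the untranslated fraction, whose ratios share the input library, was 105 ± 46.6 (SD, n = 2). It is not a measure of noise, since RNAs of that fraction also differed from the input. Between the 90th and 10th percentiles the ranges were 9.88 ± 1.49 and 9.89 ± 2.71. The highest over the lowest ratio was 1655 ± 644 in 80S and 7096 ± 7407 in untranslated RNA. Among the 5950 RNAs with an input FPKM of at least 1000, a setting chosen after the low input values were seen, the 99th to 1st percentile range was 45.5 ± 12.9 in 80S and 50.5 ± 26.9 in untranslated RNA, and the full range 695 ± 316 and 811 ± 721. When the mean of the 80S libraries was set against that of the untranslated libraries, without the input, the 99th to 1st percentile range was 75.1 and the 90th to 10th 14.1.

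**Figure D4:**
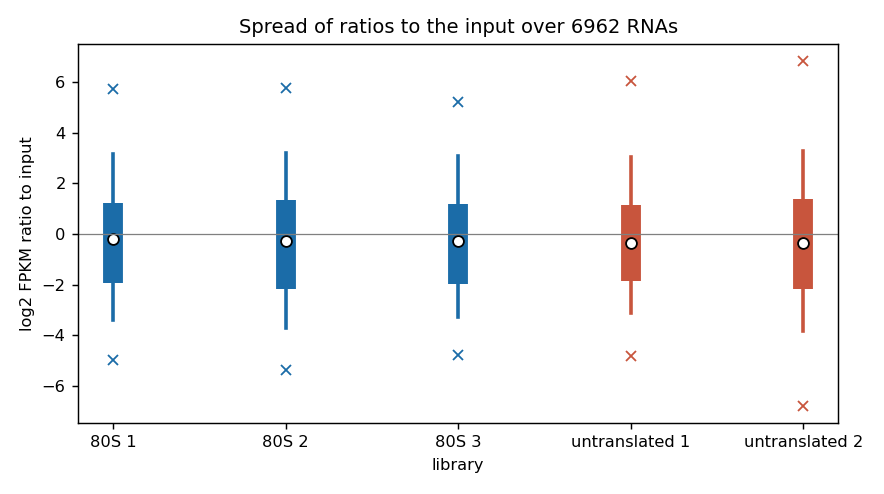
Log2 FPKM ratio to input over 6962 RNAs in each of 3 80S and 2 untranslated libraries, with thick bars from the 10th to the 90th percentile, thin lines from the 1st to the 99th, circles at the median and crosses at the lowest and highest RNA. The spread in 80S and untranslated libraries was alike, with 90th to 10th percentile ranges of 9.88-fold and 9.89-fold.

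Untranslated RNA also differed from the input. The naming rule covered no RNA of this comparison, and the RNAs given here were chosen after their values were seen. The 102 nt leader RNA of ARF2 was highest, at a log2 change of 6.43, and the PAN5 RNA that rose in 80S was lowest, at -5.80. The ARF2 RNA stood at the lowest input value, and the PAN5 change was -6.77 without untranslated replicate 1 and -4.82 without untranslated replicate 2. In limma 1209 RNAs were higher than in the input and 2397 lower at an adjusted p under 0.05 (51.8%), again with the spread of the input taken from the fractions. The higher RNAs were 33.5% of these, and 52.8% after rescaling by median ratios, so which direction prevailed depended on the scaling. RIM101 (-3.29) and SKS1 (-3.91) were lower in untranslated RNA than in the input. SKS1 in 80S did not differ from the input at the threshold (log2 0.15, limma, adjusted p = 0.759), nor did PAN5 (-1.35, adjusted p = 0.0999).

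The log2 ratios of 80S and untranslated RNA to the input, which share the input library, were correlated across RNAs. Their covariance was 0.681, against 0.0952 in 100 simulations of unchanged fractions with the same input, a difference of 0.585, while the correlation was 0.397 against 0.707. MEH1, IRS4, NSE3 and HSU1 were among 456 RNAs higher than the input in both fractions, where independent lists would share 243. MNN4, DFM1, MDL2 and SOM1 were among 952 lower in both, against 797. In 100 simulations of unchanged fractions with the same input, 0 RNAs were called in both. The simulations leave out the effects and the independent lists leave out the shared input, so neither gives the overlap to expect here. Part of the overlap may come from the shared input, which, as 1 library, could not be split. RNAs higher in both had a median input FPKM of 559 and those lower in both 4575.

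Leaders of high GC content were less abundant in 80S. Spearman's rho of GC content with the log2 ratio to input, across 6855 RNAs, was -0.250 ± 0.014 in 80S libraries (SD, n = 3). It was 0.044 ± 0.043 in untranslated libraries (SD, n = 2). Taken apart after the data were seen, the share of C had a rho of -0.394 in 80S libraries and the share of G 0.123. From the fifth of leaders with the lowest GC content (5.56% to 28.7%) to that with the highest (40.8% to 70.6%), the median log2 change of 80S against untranslated RNA went from 0.79 to -0.49. The 970 RNAs with an AUG in the reference leader had a median log2 ratio to input that was 0.27 ± 0.02 higher than that of the others in 80S and 0.08 ± 0.03 higher in untranslated RNA. An AUG in the same length of genome just upstream of the leader, a control added after the data were seen, gave 0.17 ± 0.05 and 0.12 ± 0.04. Upstream AUGs and their frames were read from the reference sequence, and whether the synthesised RNAs hold them is not given in the sources used here. Among RNAs with an upstream AUG in the reference, the 558 whose upstream reading frame ended within the leader lay 0.36 ± 0.03 above RNAs without an upstream AUG in 80S and 0.18 ± 0.01 above them in untranslated RNA. The 382 whose frame overlapped the coding sequence out of frame differed by 0.14 ± 0.04 and -0.03 ± 0.09, and the 30 in frame with it by 0.01 ± 0.15 and 0.0027 ± 0.043. These classes were not matched for leader length. The median log2 ratio to input was -0.36 for leaders of 13 to 26 nt and -0.04 for those of 75 to 115 nt in 80S. In untranslated RNA it was -0.48 and -0.10, so an effect of the frame was not separated from length. In 80S against untranslated RNA, the median log2 change was 0.34 for frames that ended in the leader, 0.32 for overlapping frames, 0.60 for frames in frame with the coding sequence and 0.16 without an upstream AUG.

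The 306 leaders with 6 or more U in a row had a median ratio to input 0.33 ± 0.07 higher than the others in 80S and 0.33 ± 0.05 higher in untranslated RNA. The 209 leaders with 8 or more A in a row gave 0.24 ± 0.06 and 0.16 ± 0.05. An A at position -3 before the start codon, present in 4287 RNAs and part of the favoured context for initiation, gave 0.01 ± 0.02 and -0.04 ± 0.01. Leader length had a rho of 0.067 ± 0.016 in 80S and 0.112 ± 0.016 in untranslated RNA, and predicted folding energy one of -0.082 ± 0.009 and -0.110 ± 0.001. Folding energy was taken over the whole leader without adjustment for its length, so the 2 features were not separated. The effects in 80S and untranslated libraries did not overlap for length, GC content, folding energy, upstream AUG and A at -3, at the smallest exact permutation p that 3 against 2 libraries allow, 0.1, without adjustment for 7 features. For the run of A the exact p was 0.3 and for the run of U 1.0. With the untranslated fraction in place of the input, the signs for length and folding energy turned, and the run of A gave -0.0073 ± 0.12 (SD, n = 3).

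**Figure D5:**
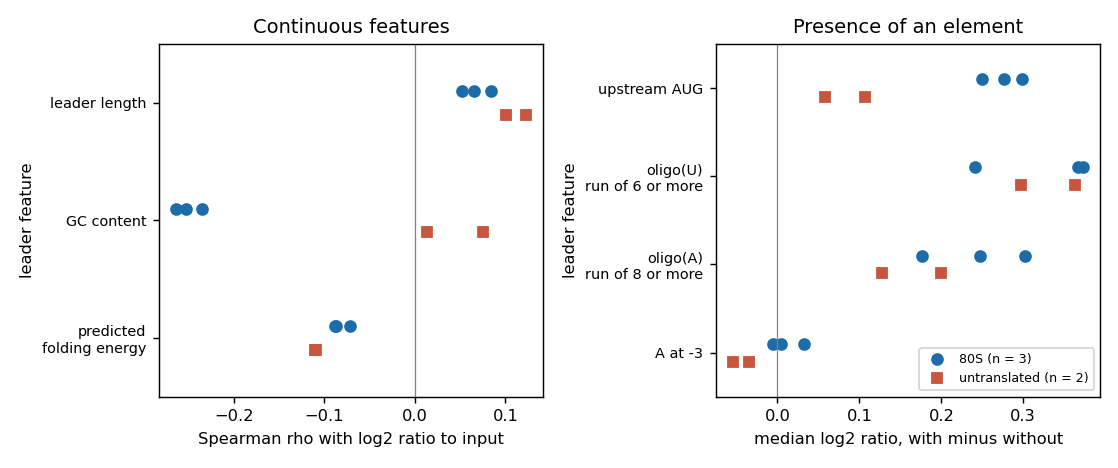
Effect of each leader feature on the log2 ratio to input in each library, as Spearman's rho across RNAs (left) or as the difference of medians between RNAs with and without an element (right), with circles for 3 80S libraries and squares for 2 untranslated libraries. GC content separated the fractions most among the 3 continuous features planned, at a mean of -0.250 in 80S and 0.044 in untranslated libraries.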

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

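The limit of an input FPKM of at least 1000 and the use of 1 RNA per gene were chosen after the data were seen, and the other settings before. The counts of RNAs for 80S against untranslated stayed within 1.5 times under each setting run, between 2343 and 2767 higher and between 1883 and 2432 lower. With an input FPKM of at least 1000, 932 RNAs were higher in 80S than in the input and 753 higher in untranslated RNA than in the input, from 1399 and 1209, among the 5950 RNAs that this limit leaves. Median-ratio rescaling gave 1825 RNAs higher in untranslated RNA than in the input. The 80S to input range was 45.5 at that input limit, in place of 98.1, and from 87.8 to 106 when an 80S library was left out. Filters at a mean FPKM of 0 or 100 removed no RNA, so they test nothing. Pairs of leaders numbered 617 to 724 higher and 584 to 699 lower for the longer leader when 1 library was left out. Where untranslated RNA was reduced to 1 library, that library was assumed to vary like the others. Low RNAs carry more error, and depth is unknown.

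Lists depended on the test. In 80S against untranslated, fry gave 9 lists higher and 5 lower, and camera without 80S replicate 3 gave 1 lower, with 0 to 1 lower and 0 higher when 1 library was left out. In 80S against input, fry gave 1 higher and 13 lower, 1 RNA per gene gave 1 lower, an estimated correlation 0 lower, and leaving out 1 library 0 to 2 lower. fry does not set a list against other RNAs, and the median log2 change of all RNAs against the input was -0.25. Its calls there included amino acid biosynthesis and genes reported with upstream open reading frames (fry, adjusted p = 0.0166 for each). Their medians lay 0.02 and 0.04 above that of all RNAs, so passing fry does not show a difference from the pool. How far the scaling accounts for the fry calls was not tested. With the untranslated in place of the input libraries as denominator, the leader effects in 80S were -0.041 ± 0.017 for length and 0.022 ± 0.011 for folding energy (SD, n = 3), both of the opposite sign. The run of A gave -0.0073 ± 0.12, within its spread of 0, and 0.024 when group means were compared. The others were -0.265 for GC content, 0.176 for an upstream AUG, 0.033 for the run of U and 0.082 for A at -3. This ratio also takes in the effects in untranslated libraries. Those were 0.112 ± 0.016 for length and -0.110 ± 0.001 for folding energy, but 0.044 ± 0.043 for GC content (SD, n = 2). Whether they differ from 0 was not tested.

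Replicate numbers were shared by 2 libraries of each fraction, too few to establish a pairing. Deviations from the group mean correlated at 0.086 for the libraries numbered 1 and 0.53 for those numbered 2, and 80S replicate 3 correlated with untranslated replicate 1 at 0.55. With a replicate block, which left 1 residual degree of freedom, 5023 RNAs passed for 80S against untranslated in place of 4904, 3517 for 80S against input in place of 3713, and 3553 for untranslated against input in place of 3606. The block gave 2767 higher and 2256 lower RNAs in the first comparison, 675 and 643 pairs of leaders, and 1 list lower in 80S against untranslated. HTB1 was past the threshold without the block and not with it (-0.70, adjusted p = 0.0604 in limma). Of the named results, no sign turned under any setting run, and 2, HTB1 and YEF3, lost their call under some.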

Other observations

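The tests in this part were added after the planned results had been seen, and of the 5 that weigh explanations, those of library bias and of input noise were chosen after the values they measure were seen. The relation of 80S recruitment with GC content lay with C. The share of C in the leader had a Spearman's rho of -0.394 ± 0.012 with the log2 ratio to input in 80S libraries (SD, n = 3) and 0.074 ± 0.020 in untranslated libraries (SD, n = 2), while the share of G had 0.123 ± 0.025 and -0.008 ± 0.026. Leaders of the 8 RNAs with the largest rise in 80S, such as RIM101 and GAL10, had a median C share of 11.6%, the 7 of the 8 with the largest fall that have a sequence 24.6%, and all leaders 16.7%. Of those 7, IBA57 had 33.3%, but GUS1, with the largest fall, had 6.67% and no 2 C in a row. The change of 80S against untranslated RNA was lower in leaders with longer runs of C, though not at each step. Its median log2 value was 1.41 in 34 leaders without C, 0.72 in 2604 whose longest run was 1 C, 0.08 in 3141 with 2, -1.20 in 884 with 3, -1.40 in 157 with 4, -1.11 in 23 with 5 and -2.17 in 12 with 6 or more. Of leaders with at most 1 C in a row 53.5% were higher in 80S and 16.1% lower in limma, and of 192 leaders with 4 or more 8.33% were higher and 70.3% lower.

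In a scan of 256 words of 4 bases over 4056 genes with 1 leader each, 88 words went with lower and 42 with higher 80S against untranslated values (permutation test with 100000 resamples, Benjamini-Hochberg adjusted p under 0.05). CCCC came lowest, with a difference of medians of -1.90, then CCCA (-1.70) and UCCC (-1.60). The 10 lowest words all held CC, and 0 of the 10 highest held a C. Words overlap and are not independent of each other. In leaders of at least 40 nt, a run of 4 C within 20 nt of the 5′ end (37 RNAs) went with a difference of -2.48 from leaders without a run, and one within 20 nt of the start codon (56 RNAs) with -1.02, and one elsewhere (66 RNAs) with -1.34. Differences between the positions were not tested.

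Leaders with a run of 4 C had a median log2 change of 80S against untranslated RNA that differed from that of the others by -1.58. A bias of reverse transcription, ligation or amplification against C that all libraries share would cancel in ratios between them, so it was not tested. One that acted on both fractions alike and not on the input would lower these leaders in untranslated RNA too. There they lay 0.25 above the others relative to the input, against -1.38 ± 0.08 in 80S. The gene or coding sequence is argued against by pairs of leaders: in 36 genes with the run only in the longer leader, the longer RNA was lower in 26 and higher in 3, and the median difference lay -2.30 from that of 1914 pairs without a run (permutation p = 1e-05, two-sided, the smallest that 100000 resamples give). A run in the same length of genome just upstream of the leader went with -0.15. As far as their names show, the synthesised RNAs lack that stretch. It could not act on them, so this value decides nothing about regional composition. A candidate explanation is then that C in a leader, as runs or as a share, lowers its recruitment to 80S ribosomes in the extract. This hypothesis was found and tested on the same data. Runs were not separated from the share of C. The median change of 80S against untranslated RNA was 1.41 in leaders without C and already 0.72 in those whose longest run was 1 C.

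The pairs with the largest differences among these 36, named after their values were seen, were those of DEF1, whose 110 nt leader had a 32.9-fold lower 80S to untranslated ratio than its 73 nt leader, TVP18 (80 and 31 nt, 29.4-fold) and TVS1 (58 and 25 nt, 24.1-fold). The 3 that went the other way were FUR4 (111 and 59 nt, 1.79-fold higher for the longer), QNS1 (66 and 38 nt, 1.62-fold) and SMY2 (95 and 22 nt, 1.57-fold). Each of these 6 passed the limma threshold. With 80S set against the input, the log2 difference had the opposite sign for SMY2 (-0.55). It kept its sign for FUR4 (0.79) and QNS1 (1.13). Runs of C are not the whole of the leader effect: the added sequences of the 5 pairs with the largest difference of all, ARF2, ENB1, POM152, SNU71 and VPS36, held no run of 3 C. Among pairs without a run of 4 C, 672 and 636 passed the threshold with the longer leader higher and lower. Such pairs can still hold runs of 3 C, and leaders whose longest run was 3 C had a median log2 change of -1.20. These 2 counts therefore do not separate runs of C from the rest of the leader.

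The second pattern is that ratios to input went together in 80S and untranslated RNA, as for MEH1 and MNN4. Linear effects of base composition, length and folding of the leader are argued against as its source, since the correlation was 0.394 before and 0.451 after a linear fit on them. The fit took up 17.3% of the variance of the 80S ratio and 2.10% of that of the untranslated ratio. It held no terms for runs of a base or for position in the leader, so effects of these were not tested. Noise of the single input library stays open, since the input has no replicate from which to measure it. The correlation was 0.223 among RNAs with an input at or above the median and 0.444 among those below, but this split is made on the denominator of both ratios, and the SD of log2 input was 0.661 at or above the median and 1.23 below it, so it decides nothing about noise. The biotin pulldown, which the label of the input does not name, could act on both fractions and cannot be separated from the fractions in this design. No biological explanation was tested.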
